A study of Mus musculus with 2 samples.

How the data were processed

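Total RNA of E13.5 mouse heart was measured by RNA-seq in 2 libraries, replicates 1 and 2 of 1 group. Per the labels' protocols, RNA was extracted with the mirVana method, the input was 10 ng, the size range was above 200 nt, and spike-in RNA was added. A protocol link in the labels names a SMARTer Ultra Low RNA kit manual. Per the labels, the replicate numbers are of biological replicates, embryos of both sexes were pooled, and the 2 tissue samples are separate entries under the same donor entry.

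The deposited files give, per the file headers and file descriptions, an expected count per gene and per transcript, which the authors made by estimating reads from transcriptome alignments, with no normalization. The deposited TPM values, per the file headers, are scaled to the same sum in each library over all listed features, spike-ins included. The files also give posterior mean counts and TPM and the bounds of a credibility interval of TPM, whose level the file headers do not state. The percent columns of the deposited transcript files are, per the file headers, the share of a gene's TPM held by each transcript. Per the deposited file descriptions, values were made from transcriptome alignments of 1 library each on mm10 with annotation M4. The column names are those that RSEM writes. The aligner, quantifier and their versions are not given in the sources used here. Since the estimate divides shared reads among near-identical features, genes with copies are uncertain. Estimated counts that are not whole mark such sharing, also in Myh7, Myh6, Nppa, Gapdh, Ldha, Mest, Igf2 and Gnas. How far it moved their values was not tested. TPM depends on all other features, so a larger share of spike-ins or globins lowers every other TPM.

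Gene identifiers were matched without version to GENCODE M21 on GRCm38, the same assembly, and 42462 of 43346 Ensembl genes matched. All but 2 of 497 list entries matched; Muc16 and Ahsp did not. The 96 spike-ins, the phiX entry and 26248 numbered features were kept out of library sizes and gene comparisons. The phiX entry held 0 reads, the spike-ins 5.96% and 2.56% of reads, and the numbered features 42 and 49 reads.

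Expected counts were rounded to whole numbers. Scaling factors came from edgeR 4.0.16 (TMM), with DESeq2 1.42.0 size factors as an alternative, in R 4.3.3. The coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design after its expression filter. Log2 ratios between replicates are of scaled counts with 0.5 added, replicate 2 minus replicate 1, and a mean count of at least 50 was required. Since each side is 1 library, no p-value was computed. List medians were placed among 10000 random lists of equal size drawn from 20 expression bins; lists with fewer than 4 members with enough reads were not placed, which left out the brain list. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

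Before the data were examined, 29 gene lists, 32 gene pairs, 30 genes for transcript shares, the main comparisons made with them and all but 3 alternatives were fixed. The sequence comparison of mitochondrial copies and 5 of the 7 tests of explanations were chosen after values were seen. Named genes follow a rule fixed then: the 20 highest nuclear protein-coding genes, up to 4 highest members of each list with members below 1 TPM where 4 or fewer, all pairs, with up to 14 in full, the 8 largest ratios in each direction with a mean count of at least 200, the transcript genes and the sex-linked genes. Genes outside it were chosen after their values were seen. They were Gm28437, Alas2, Klf1, Hemgn, Gata1, Myom2, Lmod1, Myh11, Isl1, the myogenic regulators and the genes of the closing section. Some genes that the rule names are not reported here. Alternatives covered thresholds, pseudocounts, scaling, posterior means, gene classes and leaving out either replicate.

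The methods were tested on simulated data for the comparison of replicate 2 with replicate 1, with counts drawn for the 16410 genes of the dispersion estimate and independent log2 ratios drawn for the 13766 genes from which lists were placed. A share of 0.970 of genes changed by 1.5 on the log2 scale, and 1.000 of those changed by 2, were at least 2-fold apart, against 0.00044 of unchanged genes. A simulated coefficient of variation of 0.1 was recovered as 0.100 with no changed gene and as 0.141 with 200 changed genes, so genes that differ strongly raise this value. With no list shifted, 5.36% of lists fell outside the central 95% over 20 draws.

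The depth of 36733400 and 36060765 reads gives 29.3 and 27.4 reads at 1 TPM for a 1 kb transcript. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.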

Results

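Total RNA from the heart of mouse embryos of the B6NCrl strain (a C57BL/6N substrain) at embryonic day 13.5 was sequenced in 2 libraries. They formed 1 group of 2 biological replicates, each a pool of male and female embryos, so the design holds no treated or mutant group. At this stage the ventricles are septating and the chambers are already beating. The data answer which genes the embryonic heart expressed, at what level, and how far the 2 pools differed. The estimated read counts summed to 36733400 in replicate 1 and 36060765 in replicate 2. Levels are given as TPM, a measure of transcript abundance corrected for length and depth, as mean ± SD over the 2 libraries (n = 2). Each SD also carries the general shift of TPM between the libraries (median log2 ratio 0.15, against −0.003 for scaled counts). A small SD therefore need not mean equal scaled counts. In a 1 kb transcript, 1 TPM stood for 29.3 reads in replicate 1 and 27.4 reads in replicate 2. Coordinates are on GRCm38, the assembly also called mm10.

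Globin and contractile protein genes led the nuclear protein-coding genes. The adult alpha globins Hba-a1 and Hba-a2, near-identical copies that were summed, reached 61934 ± 17767 TPM. The embryonic beta-like globin Hbb-y, on chromosome 7 from 103851749 to 103853216, stood at 26117 ± 8724 TPM, and the adult beta globins Hbb-bs and Hbb-bt together at 21685 ± 4052 TPM. The highest non-globin gene among them was Actc1, cardiac alpha actin (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548), at 9672 ± 1150 TPM. Within the same class it was followed by the myosin light chain gene Myl2 at 6763 ± 1054 TPM and the troponin T gene Tnnt2 at 4699 ± 547 TPM. Ftl1 (ferritin light chain), Atp5b (ATP synthase beta subunit), Nppa (atrial natriuretic peptide), Myl7, Ppia, Gapdh, Myl3, Tpm1, Tnni1, Tnnc1, Hba-x and Eef1a1 completed the 20 highest nuclear protein-coding genes. Of these, Eef1a1 was lowest, at 2615 ± 261 TPM.

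Protein-coding genes held 82.1% ± 3.1 of all TPM, globins 11.3% ± 3.2, the sarcomere list 4.92% ± 0.62, ribosomal protein genes 4.03% ± 0.36 and the 13 mitochondrially encoded protein genes 3.90% ± 0.23. Of 21474 protein-coding genes, 12309 reached 1 TPM in both libraries and 1167 reached 100 TPM. Spike-in RNA took 11.1% of TPM in replicate 1 and 5.04% in replicate 2, which lowered every other TPM by a different amount in each library. Some mitochondrial genes share sequence with nuclear copies on chromosome 1. The pseudogene Gm28437 (24613189 to 24613971) was assigned 10538 ± 1645 TPM, although 100% of its 50-nt windows also occur in mitochondrial transcripts. The mitochondrially encoded list had a median of 1859 TPM, led by mt-Atp6 at 10195 ± 608, mt-Atp8 at 6918 ± 389, mt-Cytb at 4386 ± 273 and mt-Nd1 at 4154 ± 159 TPM. The estimated counts of 8 of the 13 members, mt-Atp6 among them, were not whole in either library, so their values and the list median are uncertain, while those of mt-Atp8, mt-Cytb and mt-Nd1 were whole. The strand used in counting is not given in the sources used here, so genes with an overlapping or antisense partner are uncertain too.

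Sarcomere genes, which encode the contractile unit, were expressed throughout. All 29 members reached 1 TPM in both libraries and 24 had a mean of at least 100 TPM, with a list median of 639 TPM. After Actc1, Myl2 and Tnnt2 the list was led by Myl7 at 3894 ± 551 TPM. Myom2, an M-band protein gene, was lowest at 3.41 ± 0.81 TPM. Of 27 calcium handling and ion channel genes, 23 reached 1 TPM in both libraries, with a list median of 8.47 TPM. Pln (phospholamban) led at 484 ± 56 TPM, followed by the calcium pump gene Atp2a2 at 172 ± 2.5 TPM, and by Casq2 and Casq1 (calsequestrins) at 165 ± 18 and 151 ± 34 TPM. The channel genes Kcnd3 and Hcn2 stayed below 1 TPM in both libraries.

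Genes of the atrial and the ventricular list were both detected in this heart tissue. Bulk levels do not show which chamber expressed them. All 12 atrial genes reached 1 TPM with a median of 48.2 TPM, led by Nppa at 4105 ± 763, Myl7, Myl4 at 2044 ± 254 and Pam at 298 ± 47 TPM. All 12 ventricular genes did too, with a median of 103 TPM, led by Myl2, Myl3 at 3325 ± 457, Myh7 at 1746 ± 74 and Cited1 at 537 ± 52 TPM. Of 15 conduction system genes, 12 were detected, with a median of 7.85 TPM. Id2 stood at 206 ± 21 TPM, Gja5 (connexin 40) at 95.1 ± 11.4, Gjc1 at 38.7 ± 3.5 and Smoc2 at 33.7 ± 3.7 TPM, while Cntn2 was below 1 TPM. Cardiac transcription factors had a median of 16.8 TPM, with 29 of 30 members detected. Nkx2-5 (chromosome 17, 26838664 to 26845009) reached 110 ± 7.6 TPM, Gata4 86.6 ± 3.3, Smyd1 73.5 ± 4.3 and Mef2a 58.9 ± 6.3 TPM. Tbx1 was below 1 TPM in both libraries.

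Energy and growth genes were strongly expressed. All 17 glycolysis genes were detected with a median of 583 TPM, led by Gapdh at 3499 ± 287, Ldha at 2404 ± 410, Eno1 at 1596 ± 146 and Aldoa at 1595 ± 200 TPM. All 20 nuclear-encoded respiratory chain genes exceeded 100 TPM, with a median of 654 TPM, and Atp5b (4158 ± 449 TPM), Cox4i1 (1509 ± 223), Cox8a (1468 ± 216) and Atp5a1 (1440 ± 159) led. The 20 fatty acid oxidation genes had a median of 110 TPM, led by Fabp3 at 817 ± 101, Etfb at 460 ± 71, Acadl at 393 ± 51 and Acaa2 at 317 ± 24 TPM. All 23 proliferation genes were detected with a median of 74.4 TPM, with Cdk1 at 289 ± 33, Birc5 at 195 ± 25, Ccnb1 at 165 ± 23 and Cdc20 at 144 ± 15 TPM. The medians of these 4 lists lay at percentile 100 of 10000 random lists of protein-coding genes of the same size. These random lists were drawn from all protein-coding genes, detected or not, without matching on expression. Other lists, such as the sarcomere and imprinted lists, also lay at 100.

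Imprinted genes, a class expressed from 1 parental copy in at least some tissues or transcripts, were detected in 23 of 26 cases, with a median of 82.3 TPM. Parental origin was not measured here. Mest reached 2086 ± 103 TPM, Igf2 (chromosome 7, 142650766 to 142666816) 1105 ± 81, Gnas 987 ± 30 and the neighbouring non-coding H19 667 ± 68 TPM, whereas Rtl1 and Ascl2 were below 1 TPM. Growth factor genes were detected in 30 of 33 cases, with a median of 9.81 TPM. Besides Igf2 they were led by the chemokine gene Cxcl12 at 148 ± 3.7, Ece1 at 62.3 ± 3.1 and Tgfb2 at 49.9 ± 0.95 TPM, and Fgf8 and Fgf16 were below 1 TPM. Of 13 immediate early and stress genes, 11 were detected, with a median of 10.1 TPM. Jun was at 56.0 ± 4.7, Ier2 at 35.1 ± 2.3, Btg2 at 28.0 ± 3.2 and Dusp1 at 26.3 ± 1.1 TPM, with Hspa1b and Fosb below 1 TPM.

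**Figure D1:**
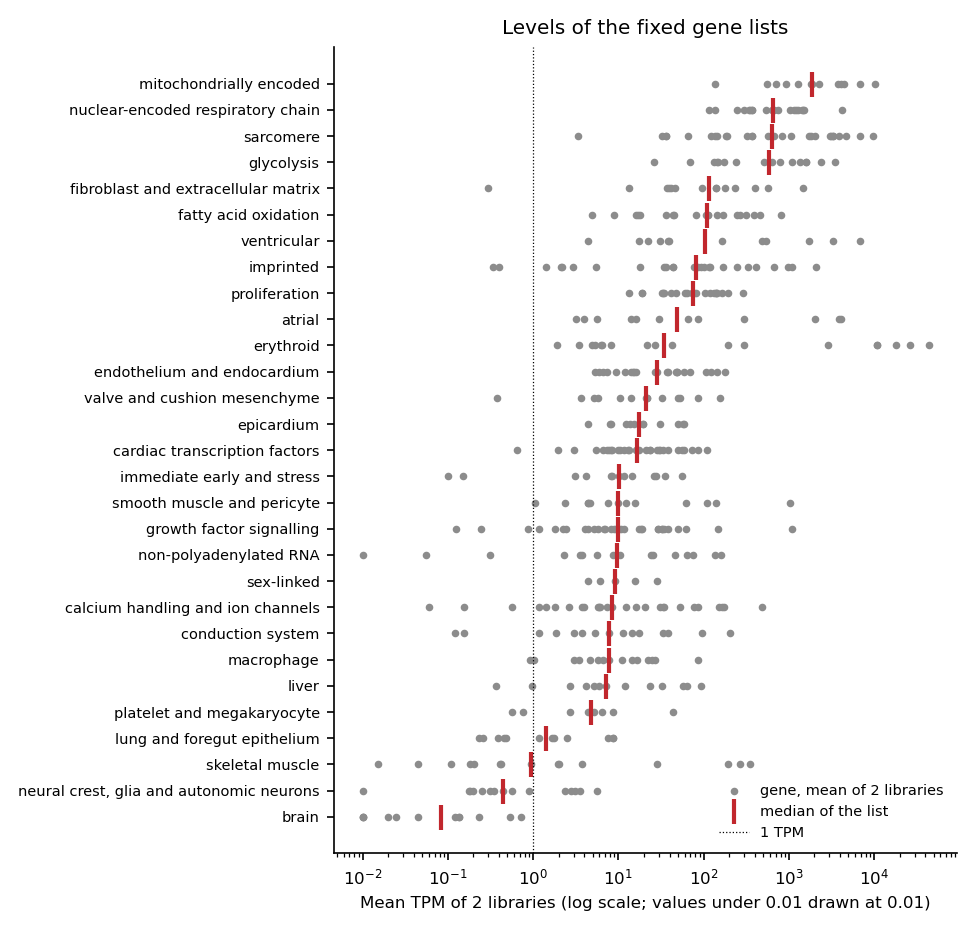
Mean TPM over the 2 libraries of each gene (grey points, log scale) in the 29 lists fixed beforehand, with the list median (red bar) and a dotted line at 1 TPM. The sarcomere median was 639 TPM and the brain median 0.082 TPM.

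Genes listed for other cell types of the heart were readily measured, though bulk tissue does not show which cells expressed them. All 23 endothelial and endocardial genes were detected with a median of 28.3 TPM, led by Ramp2 at 178 ± 20, Egfl7 at 142 ± 13, Eng at 121 ± 0.66 and Plvap at 106 ± 2.3 TPM. Among 14 valve and cushion genes, 13 were detected, with a median of 21.4 TPM. Postn (periostin) was at 157 ± 11, Lum at 87.2 ± 0.22, Vcan at 53.2 ± 8.3 TPM and Tgfb2 as above, with Has2 below 1 TPM. All 12 matched epicardial genes were detected with a median of 17.3 TPM, with Krt19 at 59.0 ± 2.9, Upk3b at 57.3 ± 9.3, Tcf21 at 50.04 ± 2.5 and Aldh1a2 at 31.2 ± 5.2 TPM. Of 14 fibroblast and matrix genes, 13 were detected with a median of 117 TPM, led by Sparc at 1462 ± 134, Col3a1 at 577 ± 48, Col1a1 at 401 ± 87 and Col1a2 at 232 ± 34 TPM. Thy1 was below 1 TPM. In the smooth muscle list, 12 of 13 genes were detected with a median of 9.84 TPM, with Acta2 at 1025 ± 96, Cnn1 at 139 ± 23, Tagln at 111 ± 25 and Smtn at 62.6 ± 0.91 TPM. The lowest of this list were Lmod1 at 1.04 ± 0.10 and Myh11 at 2.34 ± 0.28 TPM.

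Blood cell genes were also present. All 18 matched erythroid genes reached 1 TPM with a median of 34.7 TPM, among them Alas2, the erythroid enzyme of heme synthesis, at 192 ± 65 TPM. Of 15 macrophage genes, 13 were detected with a median of 7.77 TPM, led by Lyz2 at 85.5 ± 17.3, C1qb at 27.2 ± 2.5, Fcer1g at 24.9 ± 1.1 and Tyrobp at 22.5 ± 0.42 TPM, with Cd14 below 1 TPM. The platelet list had 6 of 8 genes detected and a median of 4.77 TPM. Pf4 stood at 44.2 ± 5.5 TPM, Itga2b at 8.78 ± 0.77, Ppbp at 6.44 ± 2.36 and Gp9 at 5.14 ± 1.5 TPM, and Gp1ba and Gp6 were below 1 TPM. Neural crest, glial and autonomic genes were low. Of 15, 5 were detected with a list median of 0.445 TPM, and Stmn2 at 5.64 ± 1.32, Tubb3 at 3.57 ± 0.35, Erbb3 at 3.11 ± 0.37 and Elavl4 at 2.77 ± 0.52 TPM were highest.

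Of 52 genes listed beforehand as markers of tissues other than heart, 21 were detected. They include skeletal muscle genes such as Acta1 and Ckm, which were also compared with Actc1 and Ckb as related genes of the heart. The count therefore cannot be read as an amount of other tissue. No brain gene of 12 reached 1 TPM, and the highest, Dcx, was at 0.72 ± 0.06 TPM. Of 13 liver genes, 10 were detected with a median of 7.20 TPM (2.51 in replicate 1 and 11.1 in replicate 2), led by Afp (alpha-fetoprotein) at 93.7 ± 101, Trf at 64.2 ± 40.8, Apoa2 at 57.4 ± 57.1 and Apoa1 at 32.5 ± 33.6 TPM. Hnf4a was below 1 TPM. Of 12 lung and foregut genes, 5 were detected with a median of 1.42 TPM (1.80 in replicate 1 and 0.735 in replicate 2), led by Sftpc at 8.63 ± 1.05, Epcam at 8.62 ± 0.44, Cldn6 at 7.63 ± 0.47 and Cdh1 at 2.48 ± 0.05 TPM. Of 15 skeletal muscle genes, 6 were detected, with a median of 0.94 TPM (0.58 in replicate 1 and 1.3 in replicate 2). Myl1 at 352 ± 41, Acta1 at 268 ± 58, Ckm at 195 ± 32 and Tnni2 at 28.6 ± 4.2 TPM were the highest, while of the myogenic regulators Myod1, Myf5 and Myf6 were below 1 TPM and Myog was at 1.15 and 2.90 TPM in replicates 1 and 2. At a minimum of 5 TPM the count of detected markers was 12. Among 16 genes whose RNA lacks a poly(A) tail or often does, 12 were detected with a median of 9.60 TPM, with the histone gene Hist1h4d at 162 ± 16, Rn7sk at 135 ± 29, Hist1h2bc at 74.4 ± 7.4 and Hist1h2ae at 63.2 ± 12 TPM. Hist2h3c1, Terc and Rny3 were below 1 TPM.

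Related genes, many of which replace each other as the heart matures, were compared within each library. A pair was called when both libraries had the same direction and the deposited credibility intervals of the 2 genes did not overlap in either. Of 32 pairs, 31 were called. The slow myosin heavy chain Myh7 (chromosome 14, 54970684 to 54994626) exceeded its neighbour Myh6 (54941921 to 54966927) by 2.73-fold (log2 ratio 1.45 ± 0.07). Estimated counts of both genes were not whole in either library, so shared reads make this ratio uncertain. Slow skeletal troponin I, Tnni1, exceeded cardiac Tnni3 by 1.72-fold (log2 0.78 ± 0.05). Cardiac actin Actc1 exceeded skeletal Acta1 by 36.4-fold and smooth muscle Acta2 by 9.43-fold. The ventricular light chain genes were above the atrial ones, with Myl2 over Myl7 by 1.74-fold (log2 ratio of Myl7 to Myl2 −0.79 ± 0.02) and Myl3 over Myl4 by 1.63-fold. Nppa exceeded Nppb by 24.6-fold, and Tnnt2 exceeded Tnnt1 by 8.66-fold.

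Among metabolic genes, Slc2a1, the glucose transporter GLUT1, exceeded Slc2a4 by 7.72-fold (log2 2.95 ± 0.03), Hk1 exceeded Hk2 by 5.15-fold and Ldha exceeded Ldhb by 3.01-fold. Muscle-type Cpt1b exceeded liver-type Cpt1a by 6.32-fold. The widely expressed cytochrome oxidase subunits exceeded their muscle forms, as with Cox8a over Cox8b by 12.7-fold. Among growth factors, Igf2 exceeded Igf1 by 37.7-fold. Among the remaining pairs Ckb exceeded Ckm by 1.22-fold. The log2 ratio of Atp2a2 over Atp2a1 was 6.79 ± 0.84, a wide spread, with Atp2a1 at 1.02 TPM in replicate 1 and 2.37 TPM in replicate 2. Casq2 and Casq1 were not called, at a log2 ratio of 0.14 ± 0.17. With 2 libraries no exact test can pass 0.05, so these calls carry no p-value.

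**Figure D2:**
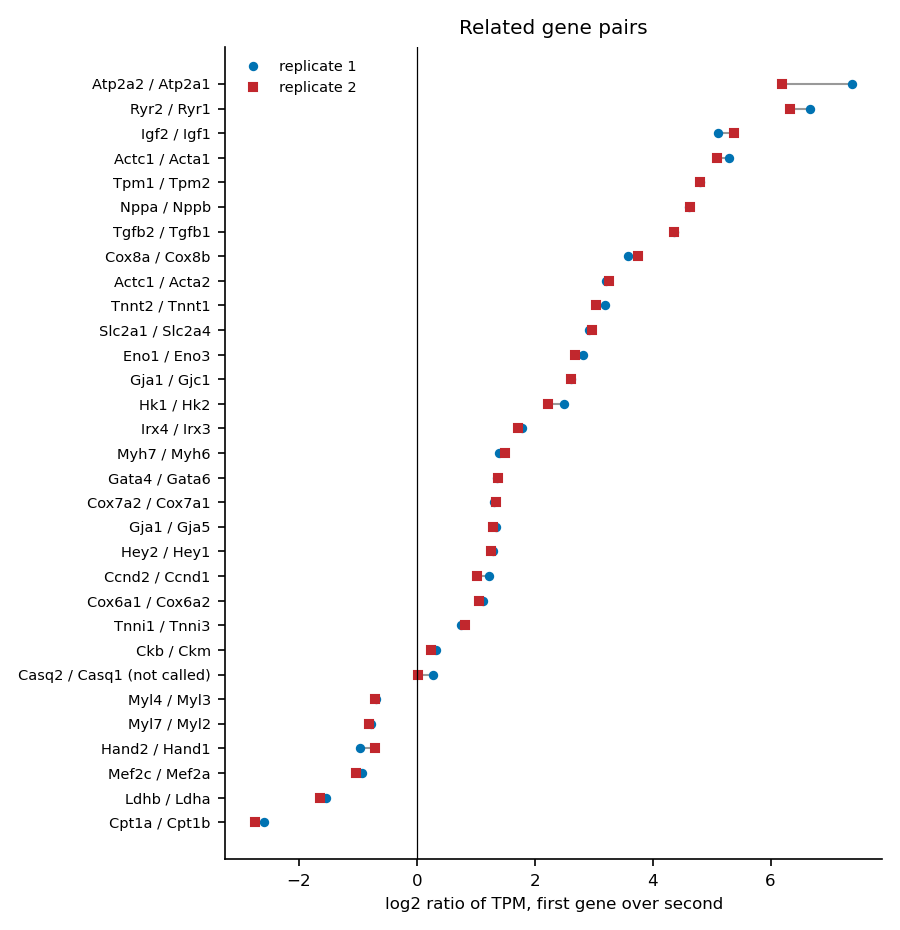
The log2 ratio of TPM of the first gene over the second for 31 of the 32 pairs, with replicate 1 as circles and replicate 2 as squares. The libraries lie close together for most pairs, for example at a mean of 1.45 for Myh7 over Myh6, and Casq2 over Casq1 was the pair not called.

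In 22 of the 30 genes chosen beforehand for transcript usage, the same transcript held over 50% of the gene in both libraries, and in 8 over 80%. In a gene with 2 listed transcripts, such as Pkm, Ryr2, Bin1 and Actn1, 1 of them must hold at least 50%. Tpm1-205 held 91.7% ± 0.8 of tropomyosin 1, Myh7-201 97.9% ± 0.2, Myh6-201 94.6% ± 1.5, Atp2a2-202 88.6% ± 0.7 and Slc8a1-201 99.3% ± 0.1. Bin1-202 and Ryr2-201 also passed 80%, the latter at 99.9% in replicate 1 and 83.3% in replicate 2. Myl6 has 1 transcript in the files. Troponin T was mixed, with a leading transcript of 1097 nt at 54.9% ± 1.1. Pyruvate kinase was led by Pkm-202 at 64.0% ± 1.6 over Pkm-201 at 36.1% ± 1.6. Leading transcripts at 50 to 80% were also found for genes that included Ttn, Ldb3, Pdlim5, Mef2a, Mef2c, Cacna1c, Rbfox2, Erbb4, Numb, Tjp1 and Actn1. Genes in which no transcript passed 50% in both libraries included Tpm2, Mef2d, Fn1, Camk2d, Mbnl1, Vegfa and Tnnt1. The shares count molecules after length correction, so that short partial models can lead, as with Ttn-215 (2159 nt, 75.2% ± 0.4) and Cacna1c-218 (954 nt, 79.0% ± 2.0).

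Liver genes were higher in replicate 2, with the largest median ratio of the fixed lists, and globin genes, a part of the erythroid list set apart after the values were seen, were lower there. Afp was at 22.0 TPM in replicate 1 and 165 TPM in replicate 2, a log2 count ratio of 2.77, and all 12 liver genes with enough reads were higher in replicate 2, with a median log2 ratio of 2.45. The embryonic globin Hbb-bh1 was 2.44-fold higher in replicate 1, Hba-x 2.13-fold, Hbb-y 1.79-fold, the summed alpha globins 1.66-fold and the summed adult beta globins 1.44-fold. Scaling by the spike-ins moved the median log2 ratio of all genes to 1.29, and the ratio of TPM moved it to 0.15. Directions are given relative to that median. On the spike-in scale itself lists and genes given as lower in replicate 2 by less than that shift turn to higher, the globins among them, with Hba-x at 0.20 and Hbb-bh1 near 0. Each replicate is 1 library, so these differences have no replicate check.

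Between the libraries, Pearson's r across 43346 genes was 0.995 and Spearman's rho 0.949 for log2(TPM + 1), where genes are not independent replicates. The biological coefficient of variation was 0.0887 over 16410 genes. Counts differed by more than sampling noise (chi-square per degree of freedom of 25.2 over 13766 genes), so that the libraries are not 1 library deposited again. Among those 13766 genes, 102 were at least 2-fold higher in replicate 2 and 37 at least 2-fold lower. Leaving out liver and erythroid genes gave 87 and 35, an alternative chosen after seeing the data. On the spike-in scale the counts were 12822 and 8. With TMM scaling they depended on the minimum mean count, at 426 and 294 for 10 and at 28 and 7 for 200.

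**Figure D3:**
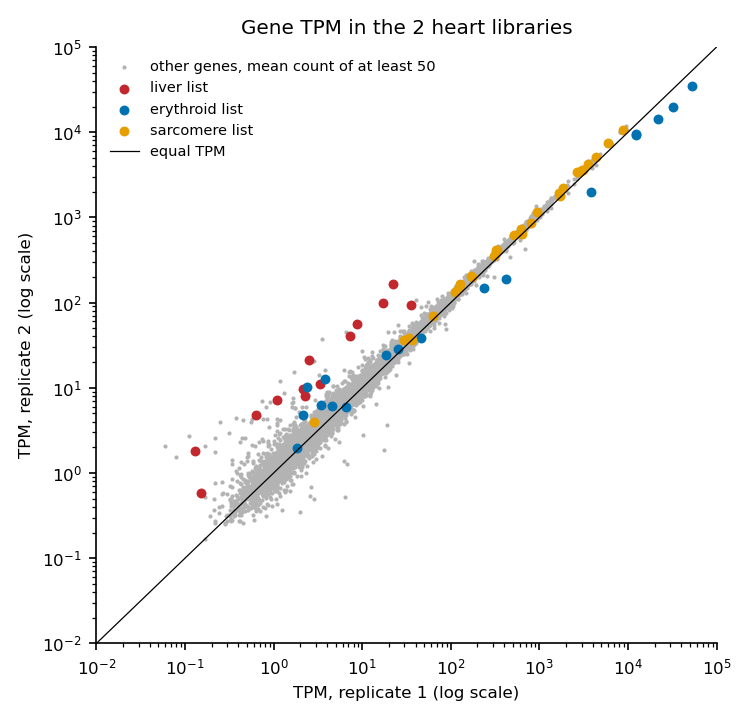
TPM of each gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, with liver, erythroid and sarcomere lists in colour and a line of equal TPM. Liver genes lie above the line, such as Afp at 22.0 and 165 TPM.

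The 8 protein-coding genes with the largest excess in replicate 2, among those with a mean count of at least 200, encode proteins that hepatocytes secrete. They were Serpina6 (9.69-fold), Serpinf2 (8.91-fold), Apom (8.12-fold), Ambp (7.65-fold), Afp (6.82-fold, chromosome 5, 90490737 to 90508907), Fgb (6.78-fold), Itih2 (6.76-fold) and Apob (6.67-fold). The 8 with the largest deficit included the globins Hbb-bh1 and Hba-x. The others were Tom1 (4.02-fold higher in replicate 1), Ccl21a (2.12-fold), Gdf10 (2.02-fold), Hsd3b6 (2.01-fold), Tent5c (1.89-fold) and Pdzk1ip1 (1.81-fold). Estimated counts of Tom1, Ccl21a and Hsd3b6 were not whole, which marks reads shared with other features, so these 3 are uncertain. On the spike-in scale Tom1 stayed lower in replicate 2 at −0.72, while the other 7 turned from lower to higher, by a log2 ratio of 0.43 or less.

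Of 28 lists with at least 4 members at a mean count of 50, 18 had a median ratio outside the central 95% of 10000 random lists matched on expression. The epicardial list was lower in replicate 2 (median log2 ratio −0.36, all 12 members), as were fibroblast and matrix genes (−0.27, all 13 members) and macrophage genes (−0.28, 13 of 14). The medians of the lung and foregut (−0.27, 6 of 7 members lower), endothelial (−0.09, 17 of 23), imprinted (−0.06, 19 of 24) and growth factor (−0.06, 21 of 31) lists were also lower. Conduction (−0.15) and valve (−0.09) members went both ways, with 6 of 12 and 7 of 13 lower. The erythroid list had a median of −0.29, with 12 members lower and 6 higher, Klf1 (log2 1.59), Hemgn (1.95) and Gata1 (1.17) among the latter. Higher in replicate 2 were skeletal muscle (0.25, all 8), platelet (0.24, all 7), atrial (0.12), sarcomere (0.10, 24 of 29), respiratory chain (0.09, 19 of 20) and glycolysis (0.08) genes. Inside the central range were ventricular (0.08), non-polyadenylated (0.06), smooth muscle (0.05), proliferation (0.04), fatty acid oxidation (0.03), immediate early (−0.01), calcium and ion channel (−0.01), mitochondrially encoded (−0.03), transcription factor (−0.03) and neural crest (−0.14) lists. The lung and foregut, endothelial, platelet and glycolysis lists moved inside the range on the ratio of TPM, as did the valve, imprinted and growth factor lists against random lists not matched on expression. At a mean count of at least 200 the conduction list turned to 0.03, inside the range, and the lung and foregut and platelet lists had too few members to place. Members of a list vary together, which random lists do not, so the percentiles describe these libraries only.

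Xist and the Y-linked genes were detected in both libraries, whose labels give embryos of both sexes. Xist, transcribed from the inactive X chromosome, was at 6.40 TPM in replicate 1 and 11.98 TPM in replicate 2 (log2 ratio 0.76). The Y-linked genes were lower in replicate 2, with log2 ratios of −0.61 for Ddx3y, −0.52 for Eif2s3y, −0.52 for Kdm5d and −0.43 for Uty, and the sex-linked list had a median of −0.52. The spike-in RNA gave 2187580 reads in replicate 1 and 923580 in replicate 2, a 2.37-fold difference.

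**Figure D4:**
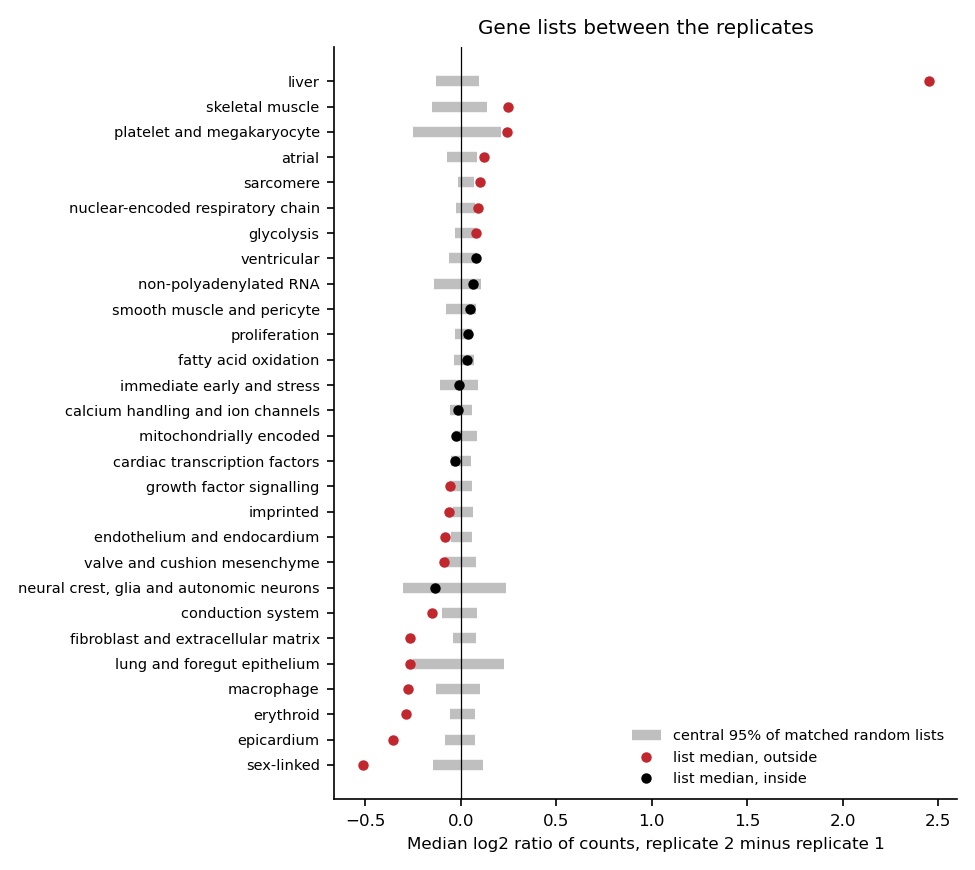
Median log2 ratio of counts, replicate 2 minus replicate 1, of each of 28 lists (points, red where outside) beside the central 95% of matched random lists (grey bars). The liver list stands at 2.45 and the epicardial list at −0.36, which turns to higher in replicate 2 on the spike-in scale.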

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

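The tests of counting error, of foregut tissue, of blood of 1 composition and both spike-in tests were chosen after the results were seen; the tests on a second hepatocyte and a second erythroblast list were fixed before their genes were looked at. No biological explanation was tested, since the labels give 1 group.

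Reads appeared in features outside the main measurement. The 26248 numbered features held 42 reads in replicate 1 and 49 in replicate 2, above the 3 reads that a count of 0 allows. The reads lay on 6 features in replicate 1 and on 4 in replicate 2. Of all these features, 26185 had an effective length of 0, which leaves no position for a read. The reads are reported as values only, and features without reads cannot be called absent.

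Liver genes were higher in replicate 2, with a median log2 ratio of 2.45. Counting error is argued against, since 12 of 12 members had a 95% counting interval that left out 0. The lung and foregut list did not rise with the liver genes, at a median of −0.27 with 6 of 7 members lower in replicate 2. On the ratio of TPM its median lay inside the random range, and some of its genes were detected in both libraries. The test therefore cannot exclude foregut and lung tissue carried along with liver in replicate 2. Carry-over of liver tissue is a candidate explanation: 20 hepatocyte genes outside the fixed list had a median log2 ratio of 2.33, with 19 higher in replicate 2. Of these 20, 2 reached 1 TPM in both libraries, Apoc1 at 6.94 and 11.2 TPM and Apoh at 1.09 and 3.84 TPM in replicates 1 and 2.

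Globin genes were lower in replicate 2. A different amount of blood of 1 composition, as the only cause, is argued against. It would shift alike all genes that only blood expresses. The 7 globin genes were all lower, but by different amounts, from −1.29 for Hbb-bh1 to −0.52 for Hbb-bs. Over the whole erythroid list 12 genes were lower and 6 higher, up to 1.95 for Hemgn. Whether other cells also express some of these members was not tested, so that split is weaker evidence. The other 11 erythroid genes had a median log2 ratio 0.99 above that of the globins, and 10 of them lay above every globin gene. As the globins were set apart after the values were seen, that gap alone decides nothing. Erythroblasts of a carried-over liver beside less circulating blood may have contributed, but the second erythroblast list, at a median of 0.13 with 9 of 12 genes higher, fell between the bounds set for and against it. That explanation therefore stays open, and 10 of the 12 genes reached 1 TPM in both libraries, with Rhd at 10.1 and 15.8 TPM and Trim10 at 12.4 and 10.9 TPM in replicates 1 and 2.

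Spike-in reads were 2.37-fold higher in replicate 1. Loss of some species only is argued against, since the highest log2 ratio among 47 spike-ins was −1.10. A single dosing factor is consistent with the standard deviation of 0.105 over them. Whether more mix or less tissue RNA was used was not tested.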

How the results depend on the processing

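The alternatives that leave out lists, and the centring of spike-in scaling on the median of all genes, were chosen after seeing the data. That centring gives back the reported scaling by construction and tests nothing. The count of protein-coding genes detected (9409 to 14316), pairs called (31 to 32) and lists shifted (15 to 19) stayed within 1.5 times the reported count under every alternative run. Without either replicate, protein-coding genes ranged from 12468 to 12586, pairs from 31 to 32, other-tissue markers from 23 to 25 and genes with a leading transcript from 22 to 23. The reported counts require both libraries, so by construction these counts could only stay equal or rise.

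The correlation was 0.988 with log2(TPM + 0.1), 0.988 for genes with mean TPM of at least 1, 0.997 with posterior mean TPM and 0.997 for protein-coding genes. The coefficient of variation was 0.0965 with no filter, 0.0882 at a mean count of at least 50, 0.0885 with posterior mean counts and 0.0837 for protein-coding genes. Genes at least 2-fold higher and lower in replicate 2 numbered 426 and 294 of 17103 genes at a mean count of at least 10. At 200 they numbered 28 and 7 of 11215 genes, so the share of genes 2-fold apart fell as the minimum count rose. By spike-in counts they numbered 12822 and 8. Other-tissue markers numbered 12 at 5 TPM, and genes with a leading transcript 8 at 80%.

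Spike-in scaling reversed Hbb-bh1 (0.00399), Hba-x (0.20), Ccl21a (0.21), Gdf10 (0.27), Hsd3b6 (0.28), Tent5c (0.37) and Pdzk1ip1 (0.43), because 1 factor shifts all genes. The conduction list reversed to 0.0307 at a mean count of at least 200. That minimum left out Hcn4 (−0.68) and Isl1 (−0.45), both lower in replicate 2, which moved the median. The transcription factor list moved outside the central range on the ratio of TPM (−0.07), the ventricular list at a mean count of at least 200 (0.09) and the neural crest list at 10 (−0.34). Of the pair ratios under alternatives, 126 kept their call and 2 became called. Low counts limit genes near 1 TPM, where 27 to 29 reads stand behind a 1 kb transcript.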

Other observations

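Non-coding RNAs outside the fixed lists were abundant, and were chosen after their values were seen. Rn7s1 and Rn7s2, identical copies of the signal recognition particle RNA on chromosome 12, were assigned 9138 ± 1383 and 9137 ± 1382 TPM, a split that cannot be read as separate levels. Malat1 reached 5224 ± 515 TPM, the mitochondrial ribosomal RNA mt-Rnr2 4768 ± 651 TPM and Gm42418 on chromosome 17 2761 ± 111 TPM. Embryonic globins made up 25.7% ± 1.7 of globin TPM. Besides Gm28437, the chromosome 1 pseudogenes Gm28661 and Gm29216 were assigned 4322 ± 511 and 3944 ± 663 TPM, with 100% and 97.1% of their 50-nt windows found in mitochondrial transcripts.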
